A study of Mus musculus with 42 samples.

How the data were processed

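RNA was measured in 42 libraries from sorted mouse thymic epithelial cells, in 3 subsets (cTEC, MHCII-low mTEC and MHCII-high mTEC) and 3 genotypes (Control, KO and Ski flox Control). Per the labels' protocols, 200 cells per library were sorted into SMART-Seq v4 reaction buffer, full-length cDNA was made and amplified by PCR, and libraries were prepared with Nextera XT. This chemistry does not mark the strand and adds no molecular identifiers. The deposited values are raw counts of reads per Ensembl gene, which the authors did not normalise, as the whole numbers in the table show. Per the submitters' processing notes, HTSeq 0.4.1, Picard 1.134, FastQC 0.11.3, SAMtools 1.2 and the genome build GRCm38 were used. The aligner, the annotation release, the strand setting and any filter are not given in the sources used here. The table held 53465 genes in 42 columns, with 0 summary lines, 0 identical columns and 0 columns outside the sample list. Of the gene identifiers, 53274 matched GENCODE release M21 (GRCm38), from which symbols and positions were taken, and 191 did not match and kept their identifiers.

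Each library was assigned to a group by the cell type and genotype in its labels. Replicate numbers within a group only tell libraries apart. The design, the 31 gene lists, the rule for named genes and a set of other settings were fixed before the data were examined. The design called for a fit of all 42 libraries. After the totals were seen, 2 Control libraries under a minimum of 100000 counts were left out, with 82 and 41828 counts, because both totals lie far below the lowest of the others. This departs from the design, and fits of all 42 libraries and of 41 (without only the smallest) were added as alternatives. The 40 libraries used held 3217251 to 7068077 counts. CPM were computed with edgeR from the TMM-normalised library sizes. For a gene with no count in a whole group, the least fold was computed by placing that group at 3 counts over its summed library sizes.

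Genes were tested in R 4.3.3 with edgeR 4.0.16. Of 37740 genes with any count, filterByExpr over the 9 groups (minimum count 10, minimum total count 15, smallest group 2) kept 23040. One quasi-likelihood model with a mean per group was fitted to the 40 libraries (glmQLFit, glmQLFTest, TMM factors), with a biological coefficient of variation of 1.40. Contrasts compared KO with Control, KO with Ski flox Control and Ski flox Control with Control in each subset, the subsets among Control libraries, and the KO effect between subsets. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was derived from the F statistic. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Members were also adjusted over the list alone. List medians count a gene absent from a group at its fitted value unless the bound is named. Some genes belong to more than 1 list, and 5 MHC class II genes are also maturation markers. Epcam, Enpep, Ptprc and the MHC class II genes encode or control sort markers and were not taken as findings between subsets.

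Named genes followed a rule. Ski was always given. In each KO and subset comparison the rule took up to 10 genes per direction of largest fold change among those past the threshold, with a median of at least 10 CPM in the higher group and medians ordered as the fold. It left out Xist, Y-linked and mitochondrial genes, pseudogenes and genes without a given name. Where fewer than 5 genes passed, the 5 of smallest p with such a median were given as not passing. From each list up to 4 passing members were eligible, or the 2 most abundant if none passed. Aire, Cd80, Ccl21a, Psmb11, Foxn1, Skil and Smad7 were fixed for every KO comparison. Where the rule gave more than a few genes, the text gives part of them in full and the rest by name. Some genes that the rule gave are not reported here. Genes outside the rule are said to be chosen after their values were seen.

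Single values per library (Ski, detected genes, summed lists and the Tas2r family) were compared between KO and Control with two-sided exact permutation tests of the difference in means, on log2(CPM + 1) or on gene numbers, in SciPy 1.17.1 (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3). The 18 pooled tests were adjusted together. Detected genes were also counted after thinning each library to 3000000 counts. Correlations between libraries showed an early and a late set by library number, which no label names. The boundary was chosen after they were seen. Every pooled permutation test was repeated within each set.

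Each result was also computed with settings fixed before the data were examined: RLE size factors, no count filter, a filter of 10 CPM in 5 libraries, covariates for the ratio of Xist to Y-linked expression and for detected genes, both control genotypes pooled, each library left out in turn, a fit of only the groups compared, camera with an estimated correlation, fry, lists without shared genes, DESeq2 1.42.0 and limma 3.58.1 (voomWithQualityWeights). Added after the data were seen were the fits of 42 and 41 libraries, the set as a term, and each set alone, which was also used for the gene lists of the comparisons with Ski flox Control. Trios of consecutive library numbers were also added as a block, and were shuffled within groups, and within groups and sets, to give a chance value. The same model, fitted to only the libraries of a comparison and without the set, was also run on up to 100 splits of them, the real one included. The code was tested on simulated data in which 200 genes were changed by known folds, 50 per fold, and the share recovered in each comparison is given with the results. Outlying libraries were sought with Dixon's test. Figures were drawn with matplotlib 3.10.9. Reads were not used, so exon-level coverage of Ski was not analysed.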

Results

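RNA was sequenced from 42 libraries of sorted mouse thymic epithelial cells (TEC), the stromal cells that guide T cell development in the thymus. The labels give 3 subsets: cortical TEC (cTEC), medullary TEC with low MHC class II (MHCII-low mTEC) and medullary TEC with high MHC class II (MHCII-high mTEC). Each subset has 5 libraries labelled Control, 7 labelled KO and 2 labelled Ski flox Control, and each library was made from 200 sorted cells. The series compares medullary and cortical TEC with and without a TEC-specific deletion of Ski, a transcriptional corepressor that acts on SMAD signalling downstream of TGF-beta. One MHCII-low mTEC Control library (replicate 2) held 82 counts over 61 genes, and one MHCII-high mTEC Control library (also replicate 2) held 41828 counts over 4381 genes. These 2 libraries were left out of the comparisons. The 40 libraries used held from 3217251 to 7068077 counts, which left n = 4 Control libraries in each medullary subset. No label ties a library to an animal, so p-values measure the spread between these libraries, which may be partly technical. Limits drawn from a count of 0 cover counting error only, because the reads carry no molecular identifiers. The libraries also fell into an early set of 19 and a late set of 21 by library number, a boundary chosen after the correlations between libraries were seen, and group means of single genes are pooled over both sets unless a set is named.

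The number of genes with at least 1 count was lower on average in KO than in Control in every subset. In cTEC it was 13546 ± 1782 (SD, n = 7) in KO and 15706 ± 1350 (SD, n = 5) in Control, a difference of -2160 genes (two-sided exact permutation p = 0.0429, adjusted over 18 such tests 0.239), with 4 of 7 KO libraries below every Control library. Within the early set the cTEC difference was -3020 genes (exact permutation p = 0.0571, the smallest it allows), and within the late set it was -1077 (exact permutation p = 0.2, also the smallest). In MHCII-low mTEC the means were 16488 ± 1911 (n = 7) and 18762 ± 2429 (n = 4), a difference of -2274 (exact permutation p = 0.121, adjusted 0.3), with -2776 in the early and -1622 in the late set (p = 0.4 in each). In MHCII-high mTEC they were 16737 ± 3487 (n = 7) and 19343 ± 956 (n = 4), a difference of -2605 (exact permutation p = 0.182, adjusted 0.364), with -4731 in the early set (p = 0.133, the smallest it allows) and 279 in the late set (p = 0.8). After every library was thinned to 3000000 counts the differences were -1909, -2407 and -2622 (exact permutation p = 0.0530, 0.0970 and 0.133), and the sign within each set was the same as before thinning. None of these differences passed the adjustment.

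**Figure D1:**
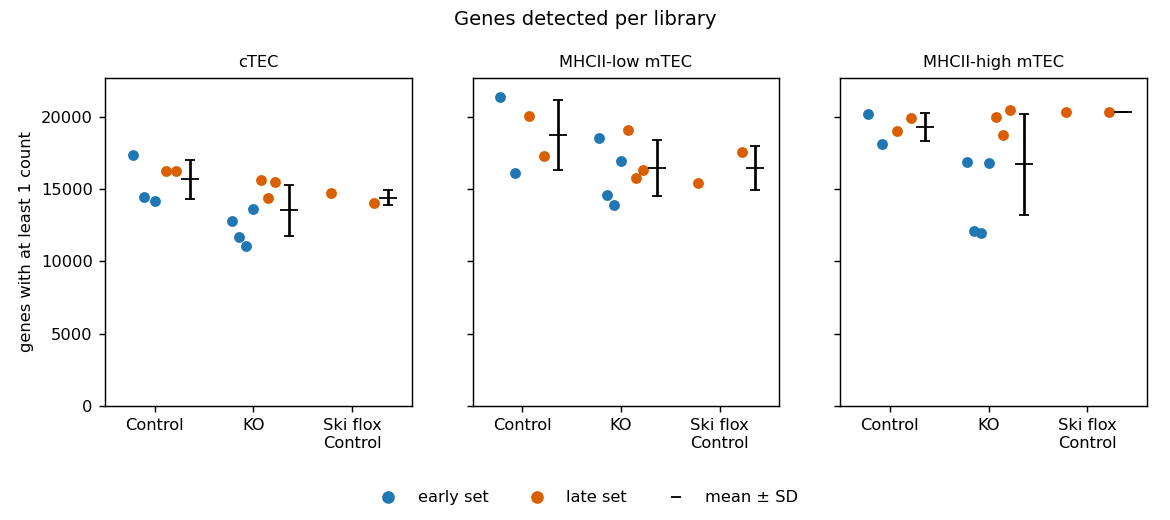
Genes with at least 1 count in each of the 40 libraries used, by subset and genotype, coloured by early or late set, with the mean ± SD of each group.

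Ski (ENSMUSG00000029050, chromosome 4, 155154075 to 155222592 in GRCm38) was counted first in every library. In cTEC the 5 Control libraries held 105, 92, 197, 92 and 19 Ski counts, and the 7 libraries labelled KO held 194, 0, 2, 220, 40, 30 and 145. In MHCII-low mTEC the Control libraries (replicates 1, 3, 4 and 5) held 102, 197, 89 and 30 counts and the KO libraries 55, 44, 9, 7, 36, 45 and 3. In MHCII-high mTEC the same Control replicates held 30, 118, 44 and 57 counts and the KO libraries 0, 57, 0, 65, 36, 3 and 33. The Ski flox Control libraries held 15 and 23 counts in cTEC, 145 and 141 in MHCII-low mTEC, and 22 and 44 in MHCII-high mTEC. A count of 0 allows up to 3 counts in a library. Levels are given as CPM, counts scaled to a common library size after TMM normalisation. Gene-level counts cannot show which exons a deletion removed, so reads from a transcript that lost only some exons would still be counted as Ski.

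Mean Ski in cTEC was 16.4 ± 16.4 CPM (SD, n = 7) in libraries labelled KO and 16.8 ± 8.97 (n = 5) in Control, a log2 fold change of -0.03 (SE 1.07, edgeR adjusted p = 1). Of the 7 cTEC libraries labelled KO, 2 lay below and 2 above every Control library. So the test does not settle whether Ski was lower there. The fold change ran from -0.48 without KO replicate 1 to 0.19 without KO replicate 2. In MHCII-low mTEC it was 6.52 ± 5.95 CPM (n = 7) in KO and 24.7 ± 15.2 (n = 4) in Control, a log2 fold change of -1.92 (SE 1.12, edgeR adjusted p = 0.796). In MHCII-high mTEC it was 6.16 ± 6.48 CPM (n = 7) and 13.4 ± 6.57 (n = 4), a log2 fold change of -1.12 (edgeR adjusted p = 1). A two-sided exact permutation test of log2(CPM + 1) gave a difference of -2.02 in MHCII-low mTEC (p = 0.0242, adjusted 0.218), with 4 of 7 KO libraries below every Control library, -2.55 in the early set (p = 0.133, the smallest it allows) and -1.54 in the late set (p = 0.4). The same exact test gave -1.68 in MHCII-high mTEC (p = 0.103, adjusted 0.3), with 5 of 7 KO libraries below every Control library, -1.95 in the early set (p = 0.4) and -1.36 in the late set (p = 0.2, the smallest it allows). In cTEC it gave -0.78 (exact p = 0.482, adjusted 0.620), with -1.57 in the early set (p = 0.571) and 0.35 in the late set (p = 0.8). The KO effect on Ski did not differ between subsets by the interaction test, with log2 differences of -1.89 (SE 1.58) between MHCII-low mTEC and cTEC, -1.08 (SE 1.57) between MHCII-high mTEC and cTEC and 0.80 (SE 1.64) between the medullary subsets (edgeR adjusted p = 1 in each). Against the 2 Ski flox Control libraries the log2 fold change of Ski in KO was 2.21 (SE 1.72, adjusted p = 0.948) in cTEC, -2.30 (SE 1.32, adjusted p = 0.686) in MHCII-low mTEC and -0.12 (SE 1.47, adjusted p = 1) in MHCII-high mTEC by edgeR.

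**Figure D2:**
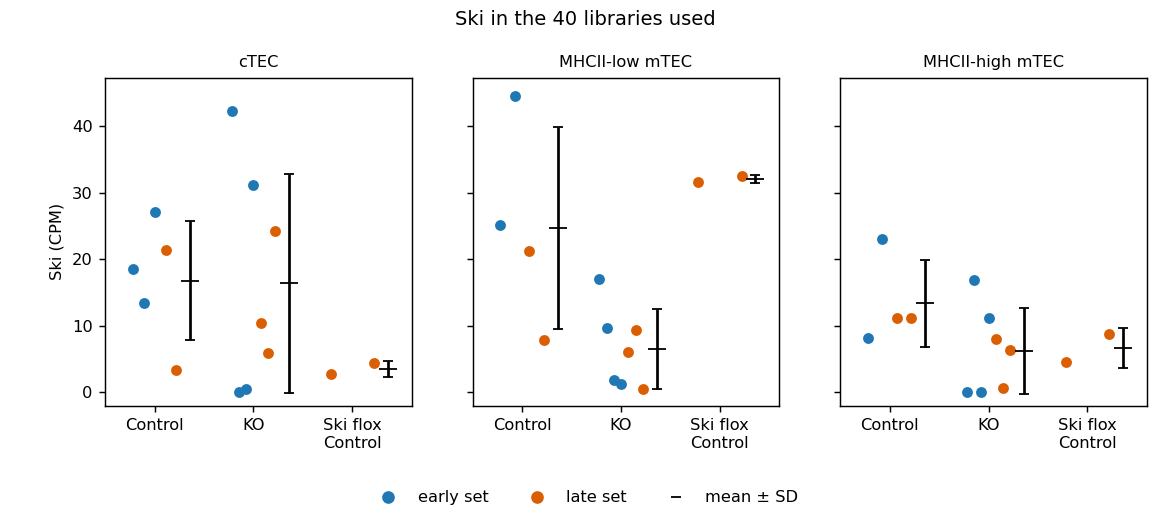
Ski in CPM in each of the 40 libraries used, by subset and genotype, coloured by early or late set, with the mean ± SD of each group.

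The comparison of KO with Control in cTEC asks which cortical genes differ with the Ski genotype. No gene of 23040 tested passed an adjusted p of 0.05 in edgeR (0 higher, 0 lower), while 2443 had an unadjusted p under 0.05, or 147 with only the groups compared. DESeq2 called 516 genes (245 higher, 271 lower), of which 229 had no count in any KO library and 217 none in any Control library, and limma voom called 17 (6 higher, 11 lower). Both of those tools called 2 genes, which were chosen after their values were seen. Nkd2, an inhibitor of WNT signalling, stood at 0.0311 ± 0.0823 CPM (n = 7) in KO and 5.96 ± 3.63 (n = 5) in Control (adjusted p = 6.27e-06 in DESeq2 and 0.00279 in limma). Rmdn2, a microtubule-associated protein gene, had no count in 7 KO libraries, at least 68.1-fold below Control (adjusted p = 0.000325 in DESeq2 and 0.0122 in limma). The genes of smallest p in edgeR did not pass. Aldh3a2, a fatty aldehyde dehydrogenase, stood at 55.0 ± 27.3 CPM in KO and 167 ± 129 in Control (log2 fold change -1.60, SE 0.42, adjusted p = 0.297). Zfp185, a LIM domain gene, stood at 0.0607 ± 0.161 and 31.4 ± 40.9 CPM (-8.35, SE 2.19, adjusted p = 0.298). Gng12, a G protein subunit gene, Ccm2, a scaffold protein, and Fosl2, an AP-1 gene, stood at 67.8 ± 13.6, 73.6 ± 26.2 and 1.36 ± 1.42 CPM in KO and at 168 ± 171, 152 ± 28.3 and 14.2 ± 10.5 CPM in Control.

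The smallest adjusted p in cTEC, 0.0834, belonged to Chga, a secretory granule gene of endocrine cells, at 0.582 ± 1.47 CPM in KO and 2170.0 ± 4852 in Control, where 1 library (Control replicate 3) held 10849.9 CPM. Single libraries moved the cTEC count between 0 and 4 genes, all named after their values were seen. Without Control replicate 1 or replicate 2 it was 1 gene (Chga), without replicate 3 it was 1 (Cdhr5, a protocadherin of intestinal brush borders), and without replicate 4 it was 2 (Chga and Cdhr5). Without Control replicate 5 it was 4 (Aldh3a2, Gdap1l1, Chga and Cdhr5), without KO replicate 1 it was 2 (Nrbp2 and 1810010H24Rik) and without KO replicate 5 it was 2 (Upp1 and Wdr59). With no count filter or with a filter of 10 CPM in 5 libraries the count was 2 (Chga and Cdhr5).

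Of the 31 gene lists, fixed before the data were examined, 1 differed between KO and Control in cTEC by camera with a preset correlation of 0.01. Enterocyte and hepatocyte-like medullary genes, which mTEC subsets that resemble gut and liver cells transcribe, rose as a list (11 of 13 measured members with a positive fold change, median log2 2.36, or 2.12 with the 5 genes absent from a group at their bound, adjusted p = 0.0291). It was not past the threshold with an estimated correlation (adjusted p = 0.925). No member passed over all genes, and 4 were higher and 1 lower adjusted over the list alone. Its most abundant member was Reg3g, an antimicrobial lectin, at 45.8 ± 109 CPM in KO and 28.3 ± 45.9 in Control. Fewer genes were detected in the same KO libraries (13546 against 15706), and the list was not past the threshold with detected genes as a covariate (adjusted p = 0.671), in the late set (0.868), with no count filter (0.0585), with only the groups compared (0.150) or with limma voom (0.509). The call was also lost without KO replicate 2 (0.823), KO replicate 3 (0.0611) or Control replicate 4 (0.0771).

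In cTEC the other lists did not pass. Adjusted over the list alone, 3 keratinocyte-like genes were higher and 2 lower, 2 AIRE-dependent self-antigens were higher and 1 lower, 2 FEZF2-dependent self-antigens were higher and 1 lower, 2 microfold-like genes were higher (list adjusted p = 0.0505), 1 ciliated and neuroendocrine-like gene was higher and 2 lower, 1 muscle-like gene was higher, 1 YAP and TAZ target was higher, and 2 immature medullary genes, 1 TGF-beta superfamily component and 3 parathyroid genes were lower. Ctsl, the cathepsin that cortical TEC use to process self-peptides, stood at 2969 ± 2391 CPM in KO (n = 7) and 2385 ± 2225 in Control (n = 5). Psmb11, the thymoproteasome subunit of cortical TEC, stood at 546 ± 350 and 680 ± 743 CPM (789 and 997 early, 223 and 203 late), and Foxn1, the transcription factor that TEC require, at 58.9 ± 60.0 and 47.7 ± 66.9. Skil, which encodes the SKI-related corepressor SnoN, stood at 72.4 ± 48.5 and 98.0 ± 51.8 CPM, and Smad7, an inhibitor of TGF-beta signalling, at 5.17 ± 4.38 and 7.37 ± 3.69. Aire, the activator of tissue-restricted genes, stood at 38.5 ± 43.4 and 41.8 ± 30.4 CPM and Cd80, a costimulatory ligand, at 29.7 ± 32.1 and 25.5 ± 26.7 (edgeR adjusted p = 1 for each of these genes). Ccl21a, of a multi-copy chemokine family, was not tested because almost no reads were assigned to it.

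In MHCII-low mTEC the same comparison asks which genes differ with the Ski genotype. In edgeR 0 genes passed, and 1639 had an unadjusted p under 0.05, where chance gives 1152. DESeq2 called 234 (135 higher, 99 lower), of which 95 had no count in KO and 126 none in Control. Limma voom called 54 (2 higher, 52 lower). Both of those tools called 6 genes, chosen after their values were seen, each with no count in 7 KO libraries. Nppc, a natriuretic peptide, was at least 82.9-fold below Control (7.13 ± 5.62 CPM, n = 4), and Neurod1, a neuroendocrine transcription factor, at least 310.2-fold (26.7 ± 51.7 CPM). Vwa5b2, the liver cytochrome gene Cyp3a11, Grxcr2 of inner-ear hair cells and Cyp2c68, another liver cytochrome, were at least 54.1-fold, 545-fold, 65.6-fold and 99.8-fold below Control (4.66 ± 7.30, 46.9 ± 89.3, 5.64 ± 8.17 and 8.59 ± 11.1 CPM), each with 1 of 4 Control libraries at 0, and Neurod1 with 2. Single Control libraries carried these limits. Without replicate 1 they were 10.2-fold for Neurod1, 12.2-fold for Vwa5b2 and 38.9-fold for Cyp2c68. Without replicate 5 they were 26.0-fold for Cyp3a11 and 18.7-fold for Grxcr2. Without replicate 4 it was 52.1-fold for Nppc. The genes of smallest p in edgeR did not pass (adjusted p = 0.639 or more). Jpt2, a regulator of calcium channels, stood at 196 ± 81.6 CPM in KO and 67.2 ± 33.8 in Control (log2 fold change 1.54, SE 0.41), and Gsdmd (gasdermin D) at 183 ± 100.3 and 70.5 ± 29.8 (1.38, SE 0.39). Tas2r121, a bitter taste receptor, had no count in 7 KO libraries and 16.7 ± 15.6 CPM in Control, at least 194-fold lower, or 109-fold without Control replicate 1. Eed, a Polycomb subunit, stood at 114 ± 45.9 and 51.1 ± 17.4 CPM, and Ndrg4 at 0.118 ± 0.233 and 11.7 ± 6.88 CPM. In the late set alone 5 genes passed (Mmp25, Glipr2, Anxa3, Ankrd35 and Phf11b).

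By camera with the preset correlation 6 lists differed between KO and Control in MHCII-low mTEC, and none did with an estimated correlation (adjusted p = 0.889 for each). AIRE mTEC-high and maturation markers rose as a list (18 of 20 members positive, median log2 0.45, adjusted p = 0.00445). MHC class II genes rose as a list (13 of 14 members positive, median log2 0.43, adjusted p = 0.00445), and 5 of them are also in the list of maturation markers. Cd74, the class II invariant chain, stood at 7493 ± 2924 CPM in KO (n = 7) and 6791 ± 2282 in Control (n = 4), with 5638 and 7625 in the early and 9966 and 5957 in the late set. NF-kappaB and RANK pathway genes, which drive medullary maturation, rose as a list (13 of 18 positive, median log2 0.23, adjusted p = 0.0195), with Nfkbia at 1463 ± 522 and 1328 ± 116 CPM. Thymic tuft cell genes fell as a list (0 of 18 members positive, median log2 -0.48, adjusted p = 0.0419). Gnat3, the taste G protein gustducin, stood at 592 ± 553 CPM in KO and 1669.7 ± 1079.8 in Control. No member of these 4 lists passed over all genes or adjusted over the list alone.

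Markers of other cells differed between the same MHCII-low mTEC libraries. Myeloid and dendritic cell markers rose as a list (14 of 16 positive, median log2 1.05, adjusted p = 0.0419), with Lyz2, a lysozyme of macrophages, at 1064 ± 729.9 CPM in KO and 678 ± 801 in Control and Tyrobp at 338 ± 286 and 235 ± 183 (193 and 286 early, 532 and 183 late). Their summed level in the late set was 2326 ± 307 CPM in KO (n = 3) and 682 ± 349 in Control (n = 2), and in the early set it was 4577 ± 5557 (n = 4) and 3150.2 ± 2541 (n = 2). Endothelial markers fell as a list (1 of 10 positive, median log2 -2.57, adjusted p = 0.0372), with Esam at 16.1 ± 8.97 and 101 ± 140.0 CPM. Neither list passed with an estimated correlation (adjusted p = 0.889), and no member passed over all genes or adjusted over the list alone. Summed over its members, the MHC class II list differed by 0.14 on the log2 scale (exact permutation p = 0.709, n = 7 and 4), with -0.34 in the early set (p = 0.4) and 0.76 in the late set (p = 0.4). The summed tuft list differed by -1.05 (exact permutation p = 0.273), with -0.99 in the early set (p = 0.8) and -0.97 in the late set (p = 0.2, the smallest it allows).

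Each of these 6 calls was lost when 1 library was left out of MHCII-low mTEC. The list of maturation markers was not past the threshold without Control replicate 1 (adjusted p = 0.114). The MHC class II list was not past it without Control replicate 1 (0.113), Control replicate 5 (0.0509) or KO replicate 6 (0.0626). The NF-kappaB list lost its call without Control replicate 1 (0.146), 4 (0.239) or 5 (0.0509) or KO replicate 7 (0.0719). The tuft list lost it without Control replicate 1 (0.114), 4 (0.168) or 5 (0.327) or KO replicate 2 (0.229), 3 (0.394) or 6 (0.0626). The myeloid list lost it without Control replicate 1 (0.207), 4 (0.271) or 5 (0.325) or KO replicate 2 (0.569), 5 (0.0623), 6 (0.0626) or 7 (0.0686). The endothelial list lost it without Control replicate 3 (0.939) or KO replicate 1 (0.0549), 2 (0.0656), 3 (0.0688) or 6 (0.0626). In the early set alone the maturation, MHC class II, NF-kappaB and tuft lists were not past the threshold (0.569, 0.838, 0.474 and 0.193), and the myeloid list turned to lower in KO (0.776). With both control genotypes pooled the 6 lists stood at 0.637, 0.669, 0.660, 0.344, 0.469 and 0.305. With detected genes as a covariate the maturation (0.173), NF-kappaB (0.173) and myeloid (0.276) lists were not past it, and the tuft list turned to higher (0.899). The tuft call was also lost with the set as a term (0.0763).

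The remaining lists did not pass in MHCII-low mTEC, and adjusted over the list alone 1 parathyroid gene was lower. Aire stood at 145 ± 205 CPM in KO (n = 7) and 64.0 ± 97.0 in Control (n = 4; log2 fold change 1.18, SE 1.23). Cd80 stood at 27.7 ± 20.5 and 13.5 ± 7.11 CPM, Foxn1 at 38.9 ± 44.7 and 13.2 ± 13.6 (67.9 and 24.8 early, 0.172 and 1.57 late), and Psmb11 at 15.5 ± 19.8 and 8.40 ± 5.98. Skil stood at 67.9 ± 32.7 and 37.6 ± 8.37 CPM and Smad7 at 5.20 ± 4.60 and 4.10 ± 3.01 (edgeR adjusted p = 1 for each).

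**Figure D3:**
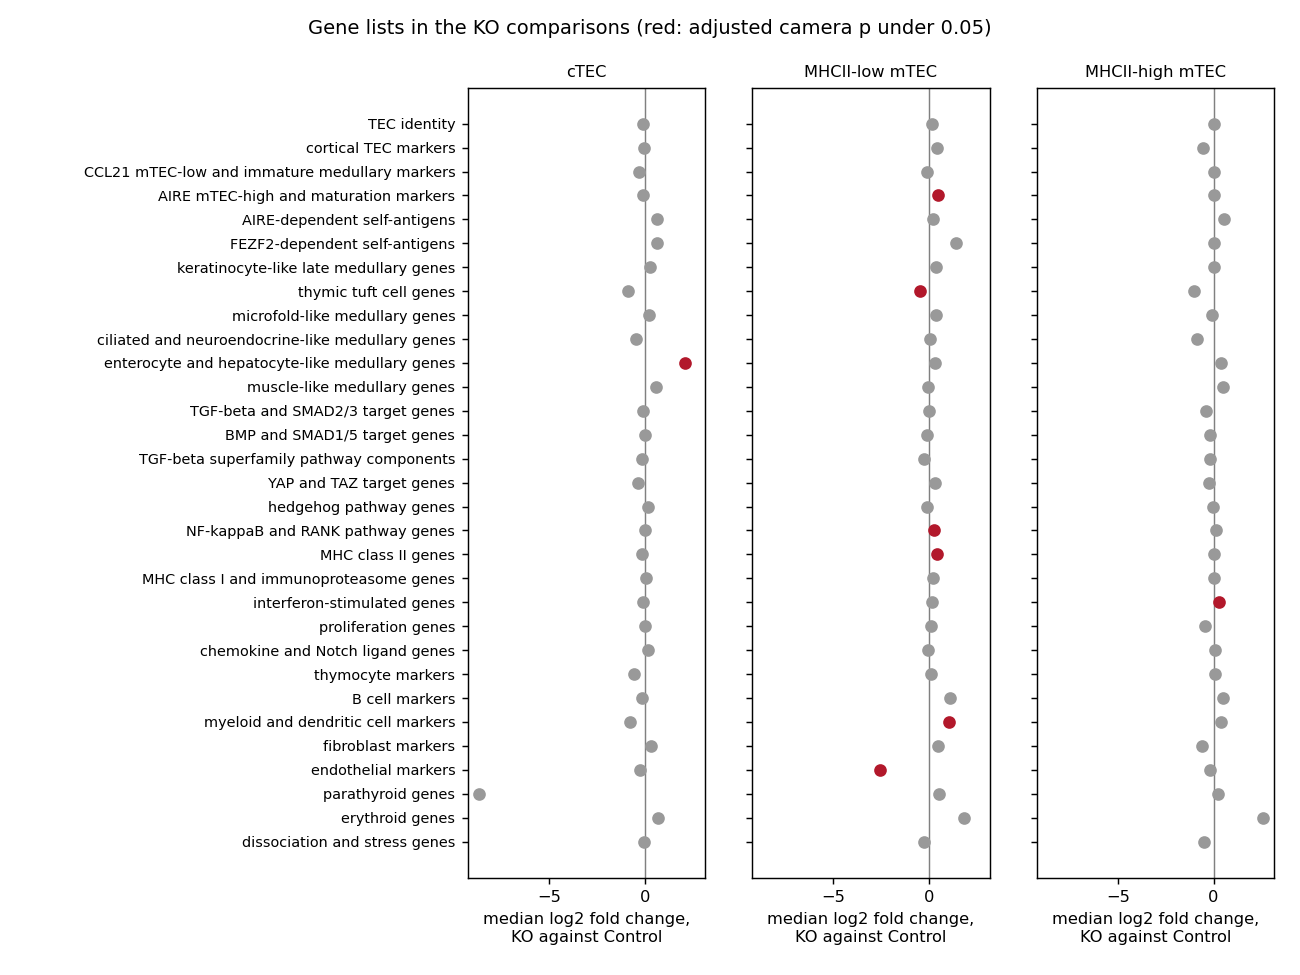
Median log2 fold change of KO against Control for the measured members of each of the 31 lists, with genes absent from a group at their bound, in the 3 subsets. Red marks an adjusted camera p under 0.05 with the preset correlation, reached by 1 list in cTEC, 6 in MHCII-low mTEC and 1 in MHCII-high mTEC.

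In MHCII-high mTEC the comparison asks which genes of the mature, Aire-expressing subset differ with the Ski genotype. In edgeR 0 genes passed (1586 had an unadjusted p under 0.05), DESeq2 called 146 (101 higher, 45 lower), of which 43 had no count in KO and 97 none in Control, and limma voom called 22 (8 higher, 14 lower). Both of those tools called Tmem252, at 14.0 ± 14.9 CPM in KO (n = 7) with no count in 4 Control libraries and at least 83.6-fold higher, and Gm5622, with no count in 7 KO libraries and 2 of 4 Control libraries (44.2 ± 75.5 CPM) and at least 476-fold lower, or 72.8-fold without Control replicate 1, both chosen after their values were seen. The genes of smallest p in edgeR did not pass (adjusted p = 0.660 or more). Ifi47, an interferon-inducible GTPase, stood at 330.4 ± 115 CPM in KO and 171 ± 43.4 in Control (log2 fold change 0.95, SE 0.28). Cic, a transcriptional repressor, stood at 3.01 ± 3.88 and 18.9 ± 7.21 CPM (-2.64, SE 0.79), and Hipk1, a nuclear kinase, at 30.2 ± 16.3 and 106 ± 59.3 (-1.81, SE 0.58). Acy3, an aminoacylase, had no count in 7 KO libraries and 11.1 ± 8.85 CPM in Control, at least 119.7-fold lower, and Crb1, an apical polarity gene, had a log2 fold change of -5.86 (SE 1.78). In the early set alone 1 gene passed (Bin2).

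By camera 1 list differed in MHCII-high mTEC. Interferon-stimulated genes rose as a list (14 of 20 members positive, median log2 0.30, adjusted p = 0.00757) with the preset correlation, and not with an estimated one (0.936). Irf1, a transcription factor of the interferon response, stood at 589 ± 240.5 CPM in KO and 425 ± 189 in Control. No member passed over all genes or adjusted over the list alone. The call was lost without Control replicate 1 (0.311) or KO replicate 6 (0.0631), with no count filter (0.0651) and in the early set alone (0.0560). Aire stood at 730.4 ± 392 CPM in KO and 580.4 ± 160.4 in Control (log2 fold change 0.33, SE 1.18), Cd80 at 52.9 ± 34.9 and 54.8 ± 32.2, and Foxn1 at 115 ± 80.0 and 66.3 ± 57.2. Psmb11 stood at 6.37 ± 12.0 and 20.1 ± 22.4 CPM, Skil at 59.6 ± 34.2 and 58.1 ± 15.7, and Smad7 at 3.01 ± 4.17 and 6.93 ± 4.28 (edgeR adjusted p = 1 for each).

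The lists closest to SKI biology did not differ between KO and Control in any subset. TGF-beta and SMAD2/3 target genes had adjusted p = 0.811 by camera (limma) in cTEC, 0.740 in MHCII-low mTEC and 0.619 in MHCII-high mTEC, and BMP and SMAD1/5 target genes had 0.503, 0.701 and 0.825. Junb, an AP-1 gene induced by TGF-beta, stood at 861 ± 754 CPM in KO and 878 ± 318 in Control in cTEC, at 795 ± 341 and 943 ± 232 in MHCII-low mTEC, and at 833 ± 138 and 889 ± 199.6 in MHCII-high mTEC. TGF-beta superfamily components (0.503, 0.307 and 0.461), YAP and TAZ targets (0.931, 0.742 and 0.946) and hedgehog pathway genes (0.521, 0.701 and 0.946) did not pass either. TEC identity genes had adjusted p = 0.702 in cTEC and 0.742 in MHCII-low mTEC, proliferation genes 0.706 and 0.795, and cortical TEC markers 0.700 and 0.419. Simulated changes limit what the edgeR tests of single genes can show: in cTEC 2%, 26%, 44% and 60% of genes changed 2-, 4-, 8- and 16-fold were recovered (50 genes each). The shares were 0%, 26%, 40% and 52% in MHCII-low mTEC and 2%, 34%, 42% and 60% in MHCII-high mTEC. No share here or below was split by expression level, so none speaks for genes of low CPM.

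The KO effect was then compared between subsets with interaction tests. In edgeR 0 genes passed for any pair of subsets, with 1701 genes at an unadjusted p under 0.05 between MHCII-low mTEC and cTEC, 1673 between MHCII-high mTEC and cTEC and 1421 between the medullary subsets. DESeq2 called 370, 367 and 138 genes and limma voom 24, 6 and 4. Between MHCII-low mTEC and cTEC the KO effect was lower for enterocyte and hepatocyte-like genes (camera adjusted p = 0.00861) and higher for MHC class II genes (0.0268) and for myeloid and dendritic cell markers (0.00974), each with adjusted p = 0.982 with an estimated correlation. Between MHCII-high mTEC and cTEC it was higher for interferon-stimulated genes (0.00261, adjusted p = 0.984 with an estimated correlation). No list differed between the medullary subsets.

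The Ski flox Control libraries form another control group of n = 2 per subset, all in the late set. Against them KO differed in 0 genes in edgeR in each subset, with 1137, 1410 and 726 genes at an unadjusted p under 0.05 in cTEC, MHCII-low mTEC and MHCII-high mTEC. DESeq2 called 1040, 997 and 105 genes and limma voom 99, 327 and 159. Against Ski flox Control, TEC identity genes were higher as a list in KO cTEC (adjusted p = 1.83e-05, 0.346 with an estimated correlation) and in KO MHCII-low mTEC (4.52e-06, 0.330 with an estimated correlation). No list passed with an estimated correlation in any subset, over all libraries or within the late set. Within the late set the cTEC call was lost and turned to lower (0.869), and that in MHCII-low mTEC passed with the preset correlation (0.000327, 0.267 with an estimated one). MHC class I and immunoproteasome genes were lower as a list in KO MHCII-low mTEC (6.91e-08, 0.330 with an estimated correlation). So were MHC class II genes (0.00360, 0.549 with an estimated correlation), the direction opposite to that against Control. Within the late set these lists gave 1.10e-08 (0.163 with an estimated correlation) and 0.0503. Tuft cell genes were also opposite, higher in KO there within the late set (16 of 18 positive, 7.22e-05, 0.296 with an estimated correlation). Over all libraries they did not pass (0.338). Thymocyte markers were lower there over all libraries (0.00303, 0.554 with an estimated correlation) but turned to higher within the late set, where dissociation and stress genes were higher (15 of 17 positive, median log2 1.01, 7.11e-07, 0.163 with an estimated correlation). Hedgehog pathway genes were higher (9e-05) and interferon-stimulated genes lower (1.83e-05) in KO cTEC (0.0783 and 0.119 with an estimated correlation). The list of maturation markers was lower by its test in KO MHCII-low mTEC (0.0152, adjusted p = 0.549 with an estimated correlation), and within the late set (4 of 20 positive, median log2 -0.59, 7.23e-05, 0.267 with an estimated correlation). Proliferation genes were lower in all 3 subsets (0.0161, 5.64e-05 and 0.0194, with adjusted p = 0.811, 0.503 and 0.943 with an estimated correlation), a call lost in MHCII-low mTEC within the late set (0.366).

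The labels do not say how the 2 control genotypes differ. They were set against each other as a background for the KO comparisons. In edgeR 0 genes differed in any subset (1090, 1275 and 435 at an unadjusted p under 0.05), DESeq2 called 959, 779 and 93 and limma voom 275, 1342 and 165. In MHCII-low mTEC 16 lists differed by camera with the preset correlation, in cTEC 7 did and in MHCII-high mTEC none did, and none passed with an estimated correlation. Within the late set 14, 10 and 5 did, and 3, 0 and 0 with an estimated correlation. The 5 in MHCII-high mTEC included tuft cell genes, lower in Ski flox Control (0 of 18 positive, 9.66e-06, 0.840 with an estimated correlation). In Ski flox Control MHCII-low mTEC, MHC class I genes were higher as a list (1.53e-09) and so were MHC class II genes (1.69e-06, 14 of 14 members positive), with adjusted p = 0.195 with an estimated correlation for each. Thymocyte (0.000218), B cell (0.0415) and myeloid and dendritic cell markers (0.00479) were higher in the same libraries (0.414, 0.500 and 0.355 with an estimated correlation). Within the late set thymocyte markers turned to lower (0.809), so that call rests on the early Control libraries, and B cell markers did not pass (0.423). TEC identity genes were lower there (4.48e-05, 0 of 15 positive, 0.195 with an estimated correlation), and in Ski flox Control cTEC (0.000754, 0.510 with an estimated correlation). Within the late set (n = 2 and 2) the call in MHCII-low mTEC held (4.19e-06) and that in cTEC turned to higher (0.387). The 3 in MHCII-low mTEC were MHC class I genes (1.85e-14, 0.0187 with an estimated correlation), maturation markers (1.24e-11, 0.0262) and myeloid markers (3.74e-10, 0.00995; 15 of 16 positive, median log2 1.79). MHC class II genes held (9.23e-09, 0.130 with an estimated correlation), and dissociation and stress genes were lower (4.91e-06, 0.126 with an estimated correlation). So the difference between the control genotypes in MHCII-low mTEC passed for more lists than the difference between KO and Control, 16 against 6, and 14 against 11 within the late set.

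The comparison of MHCII-low mTEC with cTEC among Control libraries asks which genes separate these medullary cells from cortical cells. In edgeR 178 genes passed (162 higher and 16 lower in mTEC), with 4125 at an unadjusted p under 0.05, and DESeq2 called 1521 and limma voom 2572. Several genes had no count in the 5 cTEC libraries, so only the least fold is given. Cnfn, a cornified envelope gene, stood at 192 ± 282 CPM in mTEC (n = 4), at least 1899-fold higher, and Apoa1, the main HDL apolipoprotein of liver and gut, at 179 ± 240.3, at least 1772-fold. The bitter taste receptor gene Tas2r105 stood at 175 ± 81.4 CPM (at least 1732-fold) and the pancreatic trypsin inhibitor gene Spink1 at 155 ± 103 (at least 1533-fold), and the muscle transcription factor gene Myog was at least 397-fold higher. Ceacam10, a secreted adhesion molecule, stood at 61.2 ± 56.9 CPM (at least 607-fold), Dsg1a, a desmosomal cadherin of skin, at 24.2 ± 17.2 (at least 239.7-fold), Psors1c2 and Lypd2 at 93.2 ± 105 and 80.1 ± 81.8, Klk1, a kallikrein, at 78.2 ± 121, and Mei4, a meiotic recombination gene, at 41.4 ± 37.6. Without mTEC replicate 5 the limit was 543-fold for Cnfn and 661-fold for Apoa1. Without replicate 1 it was 388-fold for Ceacam10. Gp2, of microfold cells, stood at 944 ± 794 CPM in mTEC and 1.12 ± 2.42 in cTEC (log2 fold change 9.69, SE 1.95, adjusted p = 0.0123), and Ccl20, a chemokine, at 458 ± 428 and 0.637 ± 1.43 (9.45, SE 1.86, adjusted p = 0.0105). Cldn3, a tight junction protein of medullary TEC, stood at 296 ± 110.4 and 4.85 ± 4.97 CPM (5.92, SE 1.27, adjusted p = 0.0190).

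Genes lower in MHCII-low mTEC than in cTEC were Mmp25, a membrane-bound metalloproteinase, at 0.0565 ± 0.113 and 79.2 ± 55.3 CPM (log2 fold change -9.86, SE 2.42, adjusted p = 0.0415), Rcsd1, an actin capping regulator, at 55.6 ± 28.2 and 374 ± 128 (-2.75, SE 0.58, adjusted p = 0.0167), and Poglut1, a Notch glycosyltransferase, at 113 ± 48.2 and 571 ± 314 (-2.34, SE 0.54, adjusted p = 0.0293). Tapbp, the tapasin of the peptide-loading complex, stood at 158 ± 54.3 and 478 ± 295 CPM (-1.59, SE 0.39, adjusted p = 0.0415). Gtpbp1, Pithd1, Gucd1, Vps51, Ccng2, Stard7 and Fam107b were lower as well, with log2 fold changes from -2.75 to -1.89. Ptprc, a blood cell gene, stood at 309 ± 270 and 654 ± 282 CPM, so some of these genes may come from blood cells in the sort. Of 33 named genes past the threshold, 11 kept the call whichever library was left out, among them Apoa1, Spink1, Ceacam10, Mei4, S100a8, Dsg1a, Gng13, Ccl20, Scg5 and the sort marker Epcam. Among the others the highest adjusted p ran up to 0.170 (Tapbp, without cTEC Control replicate 2). The count of 178 was 72 without MHCII-low mTEC Control replicate 1 and 104 without replicate 5. It was 54 without cTEC Control replicate 2, 112 without replicate 3, 42 without replicate 4 and 54 without replicate 5. It was 1 in the early set, where 2 mTEC libraries face 3 cTEC libraries, 710 in the late set (288 higher and 422 lower in mTEC, 81 of them among the 178), 271 with the set as a term, 100 with all 42 libraries and 355 with a filter of 10 CPM in 5 libraries.

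By camera 16 lists differed between MHCII-low mTEC and cTEC, and 3 did with an estimated correlation. Enterocyte and hepatocyte-like genes were higher (13 of 13 positive, adjusted p = 7.92e-13, 0.0253 with an estimated correlation), with 2 members past the threshold over all genes (Apoa1 and Muc13) and 13 higher adjusted over the list alone. Keratinocyte-like genes were higher (15 of 16 positive, 3.76e-07, 0.0317 with an estimated correlation), with 2 past over all genes (Dsg1a and Krt1, the latter at 26.2 CPM, with 85.9 in replicate 3 and 6.34 without it, and no count in cTEC) and 8 adjusted over the list alone. Cortical TEC markers were lower (4 of 15 positive, median log2 -2.61, 2.19e-07, 0.0317 with an estimated correlation), with 0 past over all genes and 8 lower adjusted over the list alone. Thymic tuft cell genes were higher (18 of 18 positive, 4.32e-13, adjusted p = 0.0823 with an estimated correlation), with 1 past over all genes and 14 adjusted over the list alone. The former is Gng13, a taste G protein subunit. Ciliated and neuroendocrine-like genes were higher (3.25e-05, adjusted p = 0.0716 with an estimated correlation), with Scg5, a granule chaperone, at 101 ± 72.6 and 0.142 ± 0.317 CPM and 10 higher and 1 lower adjusted over the list alone. AIRE-dependent self-antigens were higher (11 of 11 positive, 4.32e-05, adjusted p = 0.0906 with an estimated correlation), with S100a8, a calgranulin of neutrophils, at 112 ± 81.1 and 0.380 ± 0.851 CPM and 9 adjusted over the list alone. Microfold-like genes (0.00398), muscle-like genes (0.00685), FEZF2-dependent self-antigens (0.00966) and CCL21 mTEC-low markers (0.00399) were higher as lists. With an estimated correlation they gave 0.231, 0.0823, 0.231 and 0.223. Adjusted over the list alone 6, 5, 5 and 2 members passed. TEC identity genes were higher as well (0.0294, adjusted p = 0.569 with an estimated correlation), a call lost without MHCII-low mTEC Control replicate 1 (0.0935) or cTEC Control replicate 4 (0.182) or 5 (0.265).

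Other lists were lower in MHCII-low mTEC than in cTEC. Thymocyte markers were lower (0 of 18 positive, adjusted p = 4.97e-07, and adjusted p = 0.231 with an estimated correlation), at a summed 2199 ± 2278 CPM in mTEC (n = 4) and 5006 ± 2456 in cTEC (n = 5), and they turned to higher in the late set (adjusted p = 0.692). Within the early set the sums were 356 ± 199.97 and 5833 ± 3014 CPM, and within the late set 4043 ± 1391 and 3764 ± 911. Proliferation genes were lower (2 of 30 positive, 1.8e-05, adjusted p = 0.312 with an estimated correlation), which cycling thymocytes also transcribe. NF-kappaB and RANK pathway genes (1.85e-05) and MHC class I genes (7.63e-05) were lower too (0.0823 and 0.223 with an estimated correlation). Adjusted over the list alone 4 and 1 members were lower. The MHC class II list, which holds sort markers, is not taken as a finding.

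The comparison of MHCII-high mTEC with cTEC asks the same of the mature medullary cells. In edgeR 256 genes passed (246 higher and 10 lower in mTEC), with 4875 at an unadjusted p under 0.05, and DESeq2 called 1708 and limma voom 2723. Of the genes with no count in 5 cTEC libraries, Crabp1, a retinoic acid binding protein, stood at 484 ± 582 CPM in mTEC (n = 4), at least 4798-fold higher. The calcitonin gene Calca stood at 173 ± 84.1 CPM (at least 1715-fold), the glucagon gene Gcg at 163 ± 255 (at least 1613-fold), the neutrophil antigen gene Ly6g at 161 ± 256 (at least 1598-fold), Calb1 of neurons and kidney at 152 ± 252 (at least 1504-fold) and the pancreatic trypsinogen gene Prss2 at 112 ± 76.7 (at least 1112-fold). Tff3, a goblet cell trefoil factor, stood at 99.7 ± 115 CPM (at least 988-fold), Ceacam10 at 90.9 ± 38.7 (at least 900.5-fold), Dsg1a at 82.4 ± 31.7 (at least 817-fold, adjusted p = 5.12e-05), Psors1c2 at 106 ± 57.7 and AU015791 at 93.1 ± 150.0. Single libraries carried several of these limits. They were 1950.0-fold for Crabp1, 254-fold for Calb1 and 423-fold for Tff3 without replicate 3. They were 360-fold for Gcg without replicate 1 and 342-fold for Ly6g without replicate 4. Fezf2, a regulator of tissue-restricted genes in mTEC, stood at 504 ± 187 and 9.34 ± 11.4 CPM (log2 fold change 5.74, SE 1.42, adjusted p = 0.0379), Cldn3 at 163 ± 66.5 (5.05, SE 1.22, adjusted p = 0.0337), Ccl20 at 433 ± 201 (9.37, SE 1.85, adjusted p = 0.00739) and Gp2 at 412 ± 233 (8.50, SE 1.86, adjusted p = 0.0184).

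Genes lower in MHCII-high mTEC than in cTEC included 2 cortical markers. Cxcl12, a chemokine that attracts thymocyte progenitors, stood at 14.1 ± 17.0 and 738 ± 722 CPM (log2 fold change -5.70, SE 1.22, adjusted p = 0.0147), and Ctsl at 220.0 ± 128 and 2385 ± 2225 (-3.44, SE 0.88, adjusted p = 0.0449). The interferon-inducible Tgtp1 and Isg20 stood at 24.6 ± 13.0 and 98.6 ± 32.5 CPM in mTEC and at 121 ± 40.2 and 429.9 ± 353 in cTEC. Ucp2, Pithd1, Mpp1, Ccm2, Rab11b and Gdi2 were lower as well, with log2 fold changes from -3.05 to -1.16. Of 37 named genes past the threshold, 8 kept the call whichever library was left out, among them AU015791, Ceacam10, Rab11b, S100a8, Dsg1a, Ccl20 and Scg5. Among the others the highest adjusted p ran up to 0.121 (Mpp1 without cTEC Control replicate 3, Gdi2 without replicate 4). The count of 256 was 151 without MHCII-high mTEC Control replicate 1, 131 without replicate 3 and 132 without replicate 4. It was 94 without cTEC Control replicate 2, 93 without replicate 3, 69 without replicate 4 and 75 without replicate 5. It was 4 in the early set, where 2 mTEC libraries face 3 cTEC libraries, 143 in the late set, 612 with the set as a term, 536 with detected genes as a covariate, 484 with Xist and Y-linked genes as a covariate, 466 with a filter of 10 CPM in 5 libraries and 495 with only the groups compared.

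**Figure D4:**
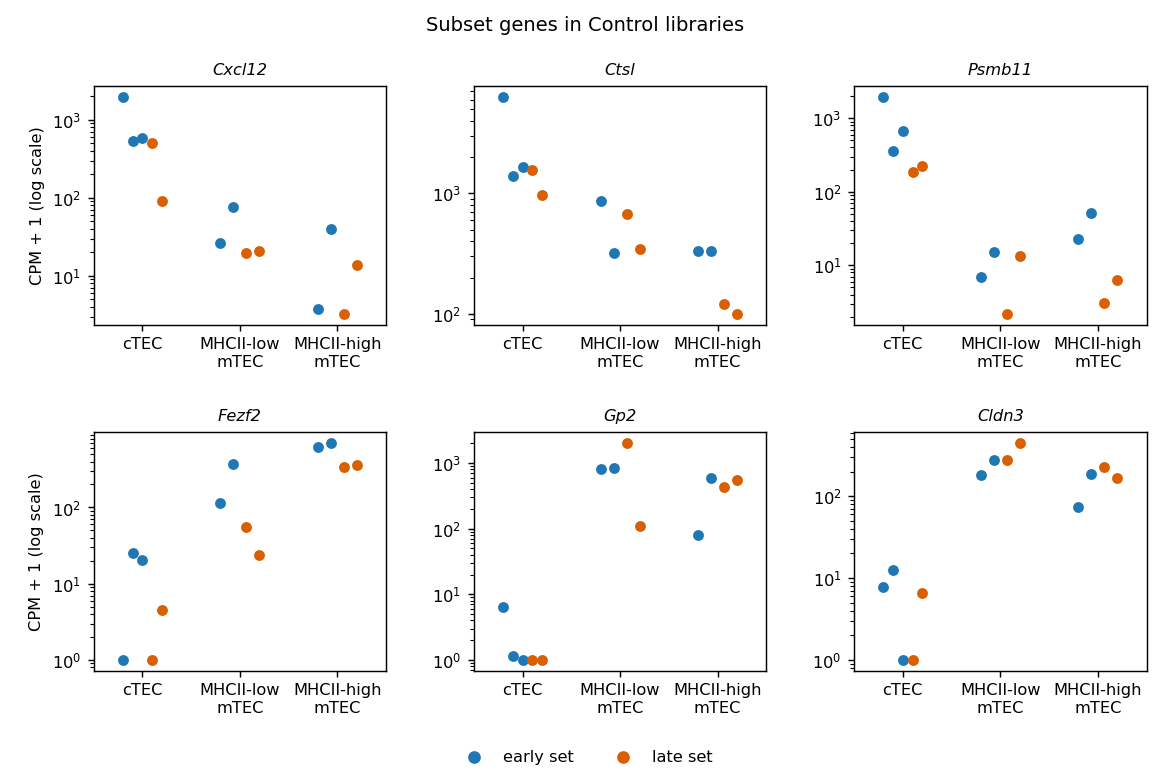
CPM plus 1, on a log axis, of 6 subset genes in each Control library, coloured by early or late set. Cxcl12, Ctsl and Psmb11 are highest on average in cTEC (738, 2385 and 680 CPM), and Fezf2 is highest in MHCII-high mTEC (504 CPM).

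By camera 16 lists differed between MHCII-high mTEC and cTEC, and 6 did with an estimated correlation. AIRE-dependent self-antigens were higher (11 of 11 positive, adjusted p = 1.38e-07, 0.0314 with an estimated correlation), with S100a8 at 281 ± 165 CPM past over all genes and 10 members adjusted over the list alone. Keratinocyte-like genes were higher (1.13e-06, 0.0314 with an estimated correlation), with 3 past over all genes and 10 adjusted over the list alone. The 3 were Dsg1a, Krt1 and Dmkn, an epidermal secreted protein. Enterocyte and hepatocyte-like genes were higher (13 of 13 positive, 1.31e-10, 0.0314 with an estimated correlation), with 5 past over all genes and 13 adjusted over the list alone. Ciliated and neuroendocrine-like genes (1.18e-05, 0.0314 with an estimated correlation, 8 higher and 1 lower adjusted over the list alone) and muscle-like genes (0.00171, 0.0390 with an estimated correlation, 6 higher adjusted over the list alone) were higher as lists. Cortical TEC markers were lower (2 of 15 positive, median log2 -1.53, 3.58e-06, 0.0314 with an estimated correlation), with 2 past over all genes and 4 adjusted over the list alone. FEZF2-dependent self-antigens were higher (8 of 8 positive, 8.95e-05, 0.0586 with an estimated correlation), with 5 members adjusted over the list alone. Microfold-like genes (0.0005) and tuft cell genes (0.000337) were higher (0.151 and 0.474 with an estimated correlation). Adjusted over the list alone 7 and 4 members passed. Summed, tuft genes stood at 318 ± 53.0 CPM in mTEC and 227 ± 255 in cTEC in the early set (n = 2 and 3), and at 3344 ± 984 and 213 ± 5.34 in the late set (n = 2 and 2). Maturation markers, 5 of them MHC class II genes, were higher (0.0347, 0.505 with an estimated correlation, 6 adjusted over the list alone), a call lost without cTEC Control replicate 1 (0.569) or MHCII-high mTEC Control replicate 4 (0.0571) or 5 (0.0711).

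Markers of blood cells were lower in MHCII-high mTEC than in cTEC. Thymocyte markers were lower (0 of 18 positive, median log2 -2.79, adjusted p = 6.01e-10, and adjusted p = 0.151 with an estimated correlation), at a summed 1021 ± 658 CPM in mTEC (n = 4) and 5006 ± 2456 in cTEC (n = 5). The sums were 479 ± 267 and 5833 ± 3014 within the early set and 1564 ± 223 and 3764 ± 911 within the late set. B cell markers (0 of 10 positive, 0.0114, adjusted p = 0.451 with an estimated correlation) and myeloid markers (1 of 16 positive, 0.00641, adjusted p = 0.424 with an estimated correlation) were lower, the latter a call lost without MHCII-high mTEC Control replicate 1 (0.0513) or cTEC Control replicate 3 (0.09). Proliferation (0.000337), interferon-stimulated (0.000337) and MHC class I genes (0.0225) were lower as lists (0.474, 0.133 and 0.505 with an estimated correlation). Adjusted over the list alone 1 interferon-stimulated gene was higher and 3 were lower. The MHC class I call was lost without MHCII-high mTEC Control replicate 1 (0.138) or 3 (0.0970) or cTEC Control replicate 4 (0.152) or 5 (0.135).

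The comparison of MHCII-high with MHCII-low mTEC among Control libraries asks which genes differ between the medullary subsets. In edgeR 0 genes passed (1720 had an unadjusted p under 0.05), while DESeq2 called 211 and limma voom 402, and 113 passed in edgeR in the late set alone, where 2 libraries face 2. The genes of smallest p did not pass (adjusted p = 0.661 for each). Klk1b9, a kallikrein of salivary gland, stood at 61.3 ± 67.2 and 0.121 ± 0.14 CPM (n = 4 each; log2 fold change 8.71). Cep85, a centrosomal gene, stood at 467 ± 95.7 and 134 ± 98.6 CPM (1.80, SE 0.44), and Sgpp1, a sphingosine phosphatase, at 507 ± 267 and 128 ± 32.4 (1.99, SE 0.50). Slc25a38, a mitochondrial glycine carrier, stood at 139 ± 14.1 and 39.3 ± 12.8 CPM (1.82, SE 0.47) and Nsmce2, a SUMO ligase of DNA repair, at 241 ± 48.3 and 97.2 ± 37.1 (1.31, SE 0.34).

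By camera 6 lists differed between the medullary subsets, and none did with an estimated correlation. Maturation markers were higher in MHCII-high mTEC (17 of 20 positive, median log2 0.80, adjusted p = 6.74e-06, 0.273 with an estimated correlation), with Aire at 580.4 ± 160.4 CPM and 64.0 ± 97.0 in MHCII-low mTEC. The sort fixed part of this, as 5 of the 20 are MHC class II genes. NF-kappaB and RANK pathway genes were higher (15 of 18 positive, 6.74e-06, 0.273 with an estimated correlation), with 2 members adjusted over the list alone. Nfkbia, the inhibitor that NF-kappaB induces, stood at 2359 ± 314 and 1328 ± 116 CPM. AIRE-dependent self-antigens were higher (9 of 11 positive, 0.0264, 0.431 with an estimated correlation), a call lost without MHCII-low mTEC Control replicate 1 (0.0980) or 4 (0.296) or MHCII-high mTEC Control replicate 3 (0.104). Tuft cell genes were lower (0 of 18 positive, median log2 -1.73, 5.22e-07, 0.431 with an estimated correlation), with Gnat3 at 526 ± 586 and 1669.7 ± 1079.8 CPM. Interferon-stimulated genes were lower (0.000197, 0.273 with an estimated correlation, 1 lower adjusted over the list alone). The MHC class II list was higher (7.87e-05, 0.431 with an estimated correlation) and reflects the sort. Of simulated genes changed 2-, 4-, 8- and 16-fold, 0%, 28%, 34% and 34% were recovered in this comparison.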

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

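The tests of explanations in this part, those with the early or late set and the splits were set out after the results were seen. The interactions, the comparison with Ski flox Control and the covariate for detected genes had been fixed before. Dixon's test at the 95% level was applied to 72 groups of libraries and set a library apart 11 times (3 times cTEC KO replicate 5), where chance flags about 1 in 20 groups, or 3.6 here. The mitochondrial share of counts stood far above the group in cTEC KO replicate 2 (3.37%) and in MHCII-low mTEC KO replicate 1 (3.61%). The summed tuft list stood far above the group in cTEC KO replicate 5 (473 CPM) and far below it in MHCII-low mTEC Control replicate 3 (1861 CPM). Bitter taste receptors stood at 3.12 CPM in cTEC KO replicate 5, above the rest of its group. Summed B cell markers stood at 30071 CPM in MHCII-low mTEC KO replicate 7, and summed myeloid markers at 12825 CPM in MHCII-low mTEC KO replicate 2, each far above the group. Summed parathyroid genes stood at 1.04 CPM in cTEC KO replicate 5, where the other 6 libraries held 0, so any count would be set apart. They stood far above their groups in cTEC Control replicate 3 (6639 CPM), MHCII-high mTEC KO replicate 3 (42 CPM) and MHCII-low mTEC KO replicate 6 (892 CPM).

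The KO effect differed between subsets for 4 lists by the interaction test with the preset correlation: enterocyte and hepatocyte-like genes (adjusted p = 0.00861), MHC class II genes (0.0268) and myeloid markers (0.00974) between MHCII-low mTEC and cTEC, and interferon-stimulated genes (0.00261) between MHCII-high mTEC and cTEC. None of these held with an estimated correlation. The MHCII-high mTEC Control library outside the fits (replicate 2) still held counts above the limit of 3 that a count of 0 allows: 859 for Cd74, 300 for H2-Aa, 20 for Epcam and 12 for Aire.

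In MHCII-low mTEC the MHC class II list was higher and the tuft list lower in KO than in Control by camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.889 for each). The MHC class II list passed with the early or late set as a term (0.00236) or detected genes as a covariate (0.00127). That excludes neither the set nor fewer detected genes in KO as a cause. Both tests used the preset correlation, and the summed list differed by -0.34 early and 0.76 late. The set stays open for the tuft list (0.0763). Fewer detected genes could account for it, as it turned to higher with the covariate (0.899). Myeloid cells in the sort may account for the MHC class II list: both lists were higher in KO in the late set (9.38e-11 for myeloid markers) and neither passed in the early set, although the sort excluded CD45-positive cells. An effect of the Ski genotype predicts a higher MHC class II list in KO than in Ski flox Control. The list was lower (0.00360), against that prediction. That call was lost with an estimated correlation (0.549) and within the late set (0.0503), so the effect stays open.

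In the late libraries TEC identity genes were lower (adjusted p = 1.42e-10) and thymocyte markers higher (1.60e-10, 0.139 with an estimated correlation) than in the early ones, a boundary drawn from the same expression values. More blood cells of every kind is unlikely, as erythroid genes fell (0.0189 with an estimated correlation). A lower epithelial share with more lymphocytes stays open. On the log2 scale Krt8 differed by -1.29 and Ighm by 3.28, but Epcam by -0.16 (adjusted p = 0.732). Depth cannot account for the pattern, as late libraries held on average 1.07 times the counts of early ones. No biological explanation was tested, because no label gives age, sex, animal or date.

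In cTEC Control replicate 3, Pth stood at 6007 CPM, Gcm2 at 573 and Casr at 59.0. Parathyroid cells in the sort are a candidate explanation, since 3 of the 4 genes of the parathyroid list were highest in that library (Cldn16 was 0 there). Medullary cells expressing parathyroid genes stay open as a source: of these 3 genes, 2 (Pth at 885 CPM and Casr at 27.4) were also found at sizeable levels in an mTEC library, in 2 different libraries, while Gcm2 reached 3.49 CPM at most there. Outside the list, Kl stood at 224 CPM in the cTEC library and at most 3.77 in any mTEC library. No biological explanation beyond this was tested, and the same library decides the Chga value in cTEC (10849.9 CPM, at most 152 in mTEC).

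Each main comparison was repeated on other splits of its libraries, fitted without the other groups, so the real numbers differ from those of the 40-library fit. For KO against Control the real count of 0 fixes the outcome, so that 100 of 100 splits giving as many says nothing (highest other 2 in cTEC, 1 in MHCII-low mTEC and 1 in MHCII-high mTEC). Counted at an unadjusted p under 0.05, the real splits gave 147, 202 and 252 genes, and 86, 72 and 89 of 100 splits gave as many (highest other 1120, 1322 and 1692), so chance cannot be excluded. In cTEC the split into early and late libraries called 147 genes past the threshold, which points to a structure of these libraries. The boundary was drawn from their own correlations, so the number is no measure for the KO split. For MHCII-low mTEC against cTEC 2 of 100 splits gave as many (real 135, highest other 156), so chance is unlikely. For MHCII-high mTEC against cTEC only the real split did (1 of 100, real 495, highest other 0). For the medullary subsets the count of 0 again fixes the outcome (35 of 35, real 0, highest other 0). At an unadjusted p under 0.05 the real split gave 856 genes and 3 of 35 splits gave as many (highest other 1178), so chance cannot be excluded.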

How the results depend on the processing

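No paired analysis was possible because the labels tie no library to an animal, so a block by library number stands in as a hint from the data, not the design. Library numbers run in trios of the 3 subsets within a genotype, and 14 of 39 pairs within a trio correlated over 0.1 (lowest -0.01). Of 40 libraries 22 correlated best with their own trio among libraries of the other subsets and the same genotype, where 8.78 are expected by chance (permutation p = 0.0004) or 14.5 within early and late sets (permutation p = 0.0471). So libraries of a trio may share something, such as an animal or a day. With the trio as a block, added after the data were seen, 45 genes passed between MHCII-low mTEC and cTEC (36 of the 178), 154 between MHCII-high mTEC and cTEC (109 of the 256), and 0 between the medullary subsets and for the interactions (879, 475, 406 and 370 at an unadjusted p under 0.05). The block left 16, 16 and 6 lists past the threshold between subsets and 1, 0 and 0 with an estimated correlation. Named genes kept their side of the threshold in 9244 of 9773 values over the other alternatives, lost it in 463 and gained it in 66. None changed sign while past the threshold in either fit. Sign changes of genes past it in neither fit count as kept, and there were 309 of them with 1 library left out. Many named genes passed in no fit. Of those that passed, 11 of 33 and 8 of 37 kept the call whichever library was left out. Called lists kept theirs in 979 of 1169, lost it in 186 and reversed in 4. The added alternatives (42 libraries, 41 libraries, set as a term, early set, late set) were chosen after the data were seen. The spread between libraries limits the tests (biological coefficient of variation 1.40), and at 200 cells per library many genes had no count in a whole group. Of simulated genes changed 2-, 4-, 8- and 16-fold, 0%, 18%, 48% and 44% were recovered between MHCII-low mTEC and cTEC, and 0%, 10%, 48% and 52% between MHCII-high mTEC and cTEC.

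The number of genes past the threshold moved as follows. In cTEC KO against Control (0) it was 2 with no filter, 2 with 10 CPM in 5 libraries, 17 with voom and 516 with DESeq2. In MHCII-low mTEC (0) it was 5 in the late set, 54 with voom and 234 with DESeq2, and in MHCII-high mTEC (0) it was 1 in the early set, 22 with voom and 146 with DESeq2. For MHCII-low mTEC against cTEC (178) it was 355 with 10 CPM in 5 libraries, 100 with 42 libraries, 271 with the set as a term, 1 early, 710 late, 2572 with voom and 1521 with DESeq2. For MHCII-high mTEC against cTEC (256) it was 466 with 10 CPM in 5 libraries, 484 with Xist and Y-linked genes, 536 with detected genes, 612 with the set as a term, 4 early, 143 late, 495 with only the groups compared, 2723 with voom and 1708 with DESeq2. Between medullary subsets (0) it was 113 late, 402 with voom and 211 with DESeq2. The early and late fits hold fewer libraries. KO against Ski flox Control (0 in each) gave 99, 327 and 159 with voom and 1040, 997 and 105 with DESeq2. The control genotypes (0) gave 275, 1342 and 165 with voom, 959, 779 and 93 with DESeq2, and 4 (cTEC) and 277 (MHCII-low mTEC) in the late set. The interactions (0) gave 24, 6 and 4 with voom, 370, 367 and 138 with DESeq2, 2 (MHCII-low mTEC to cTEC) and 2 (between medullary subsets) in the late set, and 1 (MHCII-high mTEC to cTEC) with only the groups compared. Of the 178 and 256 genes, 178 and 255 were also called by DESeq2 and 160 and 245 by voom.

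The log2 fold change of Ski in cTEC (-0.03) changed sign to 0.0314 with RLE, 0.33 with pooled controls, 0.00407 with the set as a term, 0.16 in the late set and 0.0318 with DESeq2, never past the threshold. The number of lists past the threshold in KO cTEC (1) was 0 with no filter, 2 with 10 CPM in 5 libraries, 4 with Xist and Y-linked genes, 0 with detected genes, 3 with pooled controls, 2 with 41 libraries, 3 early, 0 late, 0 with voom, 6 with DESeq2, 0 with an estimated correlation and 0 with fry. In KO MHCII-low mTEC (6) it was 3 with no filter, 2 with pooled controls, 3 early, 11 late, 0 with an estimated correlation, 0 without shared genes and 0 with fry. In KO MHCII-high mTEC (1) it was 0 with no filter, 2 with 42 and 2 with 41 libraries, 0 early, 2 late, 5 with only the groups compared, 2 with DESeq2, 0 with an estimated correlation and 0 with fry. Between MHCII-low mTEC and cTEC (16) it was 3 with an estimated correlation, between MHCII-high mTEC and cTEC (16) 6 with it and 9 with fry, and between medullary subsets (6) 11 late, 0 with an estimated correlation and 0 with fry. In KO MHCII-low mTEC voom lost the maturation (0.389) and MHC class II (0.157) calls, and DESeq2 the NF-kappaB (0.11) and tuft (0.269) calls. Reversed were tuft genes in KO MHCII-low mTEC with detected genes (0.899), myeloid markers there in the early set (0.776), and, between MHCII-low mTEC and cTEC, MHC class II genes early (0.656) and thymocyte markers late (0.692). The causes were not tested.

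With 1 library left out, the genes past the threshold ran from 0 to 4 in KO cTEC, from 42 to 215 between MHCII-low mTEC and cTEC, from 69 to 224 between MHCII-high mTEC and cTEC, from 0 to 2 in cTEC and from 0 to 1 in MHCII-low mTEC against Ski flox Control, and from 0 to 0 elsewhere. Where an arm kept 1 library, it was assumed to vary like the other groups. The log2 fold change of Ski ran from -0.48 to 0.19 in cTEC, from -2.36 to -1.47 in MHCII-low mTEC and from -1.61 to -0.72 in MHCII-high mTEC. Lists past the threshold ran from 0 to 7, 1 to 8 and 0 to 5 in the KO comparisons of cTEC, MHCII-low and MHCII-high mTEC, and from 14 to 18, 15 to 17 and 5 to 10 between MHCII-low mTEC and cTEC, MHCII-high mTEC and cTEC, and the medullary subsets.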

Other observations

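Counts of bitter taste receptor genes, which tuft cells use to sense chemicals, were found together in MHCII-low mTEC. The family was chosen after its values were seen, and its enrichment was not tested. It holds 35 Tas2r genes, 33 of them on chromosome 6, and 29 were tested. Their summed level in MHCII-low mTEC Control libraries was 1230.3, 521, 1107 and 435 CPM (replicates 1, 3, 4 and 5, mean 824 ± 403, n = 4), with 20 to 31 of the genes detected per library. In cTEC Control it was 8.29 ± 11.7 CPM (n = 5) and in MHCII-high mTEC Control 182 ± 252 (n = 4). The contrast of the medullary subsets depended on the set: 876 ± 501 against 13.8 ± 11.8 CPM early and 771 ± 475 against 349.9 ± 279 late (n = 2 each). In the 7 MHCII-low mTEC KO libraries it was 190, 8.51, 0, 48.4, 782, 421 and 83.7 CPM (mean 219 ± 288), with 0 to 27 genes detected. The difference on the log2 scale was -3.66 (two-sided exact permutation p = 0.0242, adjusted 0.218), with 6 of 7 KO libraries below every Control library, -5.53 in the early set (p = 0.133, the smallest it allows) and -1.20 in the late set (p = 0.4). In MHCII-high mTEC the difference was -0.24 (exact permutation p = 0.933), with 1.16 in the early set (p = 0.667) and -1.35 in the late set (p = 0.4). In cTEC it was -1.17 (exact permutation p = 0.321), with -1.03 (p = 0.857) and -1.38 (p = 0.8). The 2 Ski flox Control libraries of MHCII-low mTEC held 40.5 ± 48.6 CPM, also below every Control library. These genes have a single coding exon and the libraries are unstranded, so reads from genomic DNA cannot be told apart.

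The early and late sets differed in 1095 genes (759 higher and 336 lower in the late set, edgeR with the set as a term, 4712 at an unadjusted p under 0.05). The boundary was drawn from correlations of the same expression values, so these numbers and p-values describe that structure and do not test it. Foxn1 fell by 3.97 on the log2 scale (SE 0.75, adjusted p = 0.00144), the keratin genes Krt8 and Krt5 fell by 1.29 (adjusted p = 0.00255) and 1.90 (adjusted p = 0.00622), and Epcam did not differ. Cd74 was higher by 0.69 (adjusted p = 0.00289), Tyrobp by 1.74 (adjusted p = 0.0295), the immunoglobulin gene Ighm by 3.28 (adjusted p = 0.00694) and Ptprc by 2.68 (adjusted p = 0.00429). As lists, TEC identity genes were lower (1 of 15 positive, median log2 -1.29, adjusted p = 1.42e-10, 0.0318 with an estimated correlation) and thymocyte markers (18 of 18 positive, median log2 1.74, 1.60e-10, adjusted p = 0.139 with an estimated correlation), dissociation and stress genes (14 of 17 positive, 0.00185, 0.439 with an estimated correlation) and B cell markers (9 of 10 positive, 0.00831, 0.287 with an estimated correlation) higher. Erythroid genes were lower (5.59e-05, 0.0189 with an estimated correlation), tuft cell genes higher (6.28e-06, 0.195 with an estimated correlation) and myeloid markers did not differ (0.492).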
